A study of Caenorhabditis elegans with 4 samples.

How the data were processed

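Pol II ChIP and input DNA came from whole L3 hermaphrodites grown at 20 °C, crosslinked with formaldehyde and sonicated, per the labels' protocols. The labels name the strain OP54, whose genotype carries a GFP-tagged egl-5 transgene, whereas its description speaks of an EOR-1 fusion and the deposited sample table names strain OP81. This conflict was not resolved here. It does not change the target of the 8WG16 antibody. Samples were grouped by their titles as Pol II ChIP (n = 2) and input (n = 2). The labels do not say that replicates came from separate cultures, so any spread between them, and any p-value that rests on it, may be technical.

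Read counts per run are those of the deposited sample table, which lists 36-base reads, the number of reads, the uniquely mapped reads and 0 reads mapped to several places for every run. The counts of the 2 runs of each input were summed. The deposited investigation file names Eland for alignment. The aligner version is not given in the sources used here. Regions were called with PeakSeq, per the file headers, which also give WormBase WS220 as the build. The values in the region lists are q-values, per the file headers, and all listed values lie below 0.01. The sample table names the merged input as the control of all 3 lists and merged ChIP alignments as the source of the combined list. Comment lines written by a coordinate conversion show that the authors moved the regions from an earlier build, with a change of internal structure in 10, 11 and 5 regions of the combined, replicate 1 and replicate 2 lists. No region was removed for this. Inputs entered only as the authors' control, so no value per region exists for them in the lists used here.

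All comparisons were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Regions were called shared when they overlapped by at least 1 bp. Shares carry Wilson 95% intervals, which cover counting error only. Chance overlap came from 1000 circular shifts of 1 list within each chromosome, with p as the share of shifts, the observed list included, that reached the observed overlap (one-sided). Strength was compared on −log10 q across pairs in which each region is the other's largest overlap, with 100000 permutations. Chromosome lengths were taken up to the last region of any list, since no WS220 sequence was used here. The mitochondrial genome was left out of the chromosome comparisons. Regions on X were tested with a two-sided exact binomial test against the share of X in that length, and the central against the outer parts of chromosomes divided into 3 equal lengths with an exact sign-flip permutation test over 6 chromosomes (64 sign patterns).

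The authors' q-values were also used to recover ranks. In each list, q multiplied by an unknown rank gives equal values for neighbouring lines with tied p-values (tolerance 1e-11), and 1 starting rank out of 2000 tried gave 2879 tied neighbours in the combined list, 2812 in replicate 1 and 3513 in replicate 2, where the next best starting rank gave at most 1. These ties begin at lines 406, 557 and 337 of the lists, and the leading p-values checked the lines before them: at the same starting rank the first 14, 10 and 2 p-values were 1 digit long, and no other starting rank gave more than 1. The number of regions tested was then the smallest whole number that makes the leading p-values 1 digit long: 14119 for the combined list, 12933 for replicate 1 and 12163 for replicate 2. The last of these rests on only 2 leading values and is less certain. The code was checked on simulated data. In 12 simulated lists with a known number of strongest regions removed it recovered that number in 12. Of 3 planted overlap shares, 3 were recovered exactly. The 12 lists were built from the authors' q-values and the recovered ranks, with the same relation of q to rank assumed. This checks that the code works and does not test whether the authors' lists follow that relation.

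Before the data were examined, the tests, the alternatives and the rule for named regions were fixed. The rule names the 10 combined regions with the lowest q and the 3 regions with the lowest q in each replicate that overlap nothing in the other. Any other region named was chosen after its values were seen. Other settings fixed then were the stronger 50% of each list by q, merging of regions within 200 bp, stricter overlap, covered bases in place of region counts, a central part of 50%, and each replicate's list alone. Comparisons that need gene positions (genes occupied, gene ends, gene lists, biotypes and gene names) were planned and not run, because the gene table at hand describes the WBcel235 assembly and the regions are in WS220. No conversion between builds was made. The effect of read depth on the lists was not tested by thinning reads, and the lists hold no value for places that missed the q-value threshold.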

Results

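RNA polymerase II was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans hermaphrodites of the third larval stage, L3, grown at 20 °C. The antibody, 8WG16, is a mouse monoclonal that binds the repeated heptapeptide at the C terminus of AMA-1, the largest subunit of the enzyme. The antibody does not bind the GFP-tagged transcription factor that the strain carries. The 4 samples were 2 Pol II ChIP replicates and 2 inputs, which are sonicated chromatin DNA without immunoprecipitation. Pol II ChIP replicate 1 held 4666552 reads, of which 3262273 were uniquely mapped (69.9%), and replicate 2 held 6486474 reads, of which 4623128 were uniquely mapped (71.3%). Input replicate 1 held 6892286 reads in 2 runs with 1912753 uniquely mapped (27.8%), and input replicate 2 held 7261361 reads in 2 runs with 1414731 uniquely mapped (19.5%). The measurements analysed were 3 lists of Pol II regions, 1 for each ChIP replicate and 1 called by the authors on both replicates merged. Each region has a position in the WS220 build and a q-value. The q-values are the authors', and regions are given by position because no gene annotation of that build was used here.

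The first question was where Pol II was called and over how much of the genome. In the combined list Pol II occupied 9051 regions that covered 6.92 Mb, or 6.91% of the 6 nuclear chromosomes. Replicate 1 had 7359 regions over 6.62 Mb and replicate 2 had 7115 regions over 4.39 Mb (mean 5.50 Mb ± 1.58, SD, n = 2). Replicate 1 therefore covered 1.51 times as many bases as replicate 2 with 1.03 times as many regions, although it had fewer uniquely mapped reads. Most regions were short, with a median width of 380 bp in the combined list (quartiles 190 and 812 bp), 406 bp in replicate 1 and 364 bp in replicate 2. The narrowest region of each list was 1 bp wide. Regions narrower than a 36-base read numbered 591 in the combined list (6.53%), 489 in replicate 1 (6.64%) and 331 in replicate 2 (4.65%). The 114 combined regions wider than 5000 bp held 10.8% of the covered bases, against 16.9% in 171 regions of replicate 1 and 6.77% in 44 regions of replicate 2.

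The lowest q-values of the combined list lay on 5 of the 6 chromosomes. The lowest belonged to a region on chromosome III, 9814901 to 9819513, 4613 bp wide (q = 5.37e-306), followed by chromosome IV, 7981110 to 7984669 (q = 2.67e-304), and chromosome I, 9720425 to 9723863 (q = 5.33e-304). Next came a 5200 bp region near the left end of the X chromosome, 1443320 to 1448519 (q = 3.18e-303), and a 5444 bp region near the right end of chromosome V, 19607295 to 19612738 (q = 5.29e-301). The other 5 of the 10 lay on chromosome I at 7015389 to 7018200 and 1047724 to 1051440, on chromosome V at 15185526 to 15188995 and 11118103 to 11124683, and on chromosome III at 12367007 to 12371702. All 10 overlapped at least 1 region in each replicate. The chromosome III region at the top of the list had q = 1.91e-220 in replicate 1 and was split into 3 regions in replicate 2, the strongest with q = 8.64e-43. The chromosome I region at 1047724 had more even values, q = 3.81e-153 in replicate 1 and q = 4.27e-134 in replicate 2. These 10 regions were not the strongest that the authors tested. Ranks recovered from the q-values place the first listed region at rank 263 in the combined list, rank 153 in replicate 1 and rank 72 in replicate 2, so 262, 152 and 71 stronger regions are not among those analysed here.

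The second question was whether both replicates marked the same places. Of the 7359 regions of replicate 1, 4255 overlapped a region of replicate 2 by at least 1 bp (57.8%, Wilson 95% interval 56.7 to 58.9). Of the 7115 regions of replicate 2, 5148 overlapped replicate 1 (72.4%, interval 71.3 to 73.4). Regions placed at random by circular shifts within chromosomes overlapped in 10.2% ± 0.441 (SD over 1000 shifts) and 11.1% ± 0.475 of cases, and no shift reached the observed share (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Chromosome V regions of replicate 1 were found again in replicate 2 in 63.7% of cases (interval 60 to 67) and those of chromosome I in 55.9% (interval 53.6 to 58.1). In the other direction the order was different, with 65.6% on chromosome V (interval 62.3 to 68.8) and 75.8% on chromosome I (interval 73.7 to 77.8). In bases, 3.16 Mb were covered in both replicates, which was 47.7% of the bases of replicate 1 and 72.0% of those of replicate 2.

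Overlap depended on how strong a region was. Of the 3039 replicate 1 regions with q between 1e-05 and 0.01, 33.3% overlapped replicate 2 (interval 31.6 to 35.0), and of the 827 with q between 1e-50 and 1e-20, 786 did (interval 93.3% to 96.3%). Replicate 2 regions of the same classes overlapped replicate 1 in 56.4% (interval 54.8 to 58.0) and 94.9% of cases (interval 92.7 to 96.4). Chance overlap was also higher for strong regions. With q below 1e-20, shifts overlapped in 19.5% of replicate 1 regions and 18.6% of replicate 2 regions. The observed shares there were 4.96 and 4.61 times chance, against 5.66 and 6.50 times for all regions. These ratios cannot be compared across strength. At the higher chance level, even complete overlap would give a lower ratio than that of all regions. Among the strongest replicate 2 regions the overlap fell again, to 64.8% of the 125 regions with q between 1e-200 and 1e-100 and to 7 of the 34 regions below 1e-200 (20.6%, interval 10.3 to 36.8). The 3 strongest replicate 2 regions outside the replicate 1 list were chromosome I, 7019576 to 7023151 (q = 1.69e-302), chromosome I, 7869660 to 7872589 (q = 6.66e-301), and chromosome III, 5874092 to 5877395 (q = 1.18e-291). The 3 strongest replicate 1 regions outside the replicate 2 list were chromosome II, 11755993 to 11757272 (q = 2.52e-306), the X chromosome, 4968936 to 4972251 (q = 1.42e-278), and chromosome II, 9335219 to 9341742 (q = 1.46e-270). None of these 6 regions overlapped the combined list either, although that list was called on both replicates merged. The combined list held 1 of the 34 strongest replicate 2 regions and 23 of the 125 in the next class. The lists lack their strongest tested regions, 152 in replicate 1, 71 in replicate 2 and 262 in the combined list. A missing partner of a very strong region therefore cannot be read as a difference between the replicates. With overlap of at least 50% of both regions required, the shares were 29.4% of replicate 1 and 30.4% of replicate 2, still above every shift. Every list was called against the same merged input, so part of the overlap may come from that shared control.

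**Figure D1:**
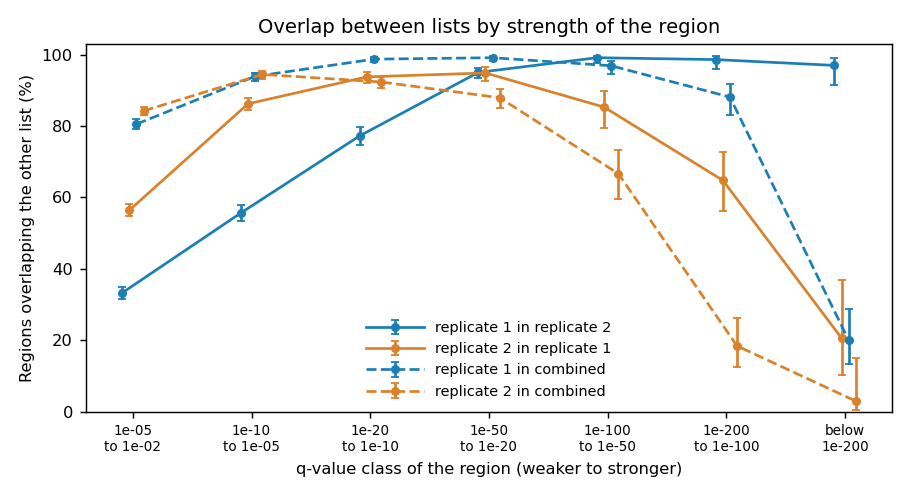
The x axis gives classes of the authors' q-value from weaker to stronger, and the y axis the percent of regions of 1 list that overlap another by at least 1 bp. Points are shares, bars are Wilson 95% intervals, solid lines are overlap with the other replicate and dashed lines overlap with the combined list. Replicate 1 regions overlapped replicate 2 in 33.3% of cases in the weakest class and 97 of 100 in the strongest, whereas their overlap with the combined list was 20.0% in the strongest class. Each list lacks its strongest tested regions, which limits what overlap in the strongest classes can show.

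Where both replicates had a region, its q-value tended to rank alike, though not closely. Across 4167 pairs of best overlapping regions, the −log10 q-values correlated with Spearman's rho = 0.695 and Pearson's r = 0.760 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The pairs are regions of the same 2 libraries and are not independent replicates. Widths of the same pairs correlated with rho = 0.737, and the ranking of q-values was not separated from that of widths. Replicate 1 had the lower q-value in 74.7% of pairs and the wider region in 78.6%, with median widths of 712 bp in replicate 1 and 438 bp in replicate 2. The median −log10 q was 11.3 in replicate 1 and 6.81 in replicate 2. Regions that lacked a partner were narrower, with a median of 199 bp for the 3104 of replicate 1 and 226 bp for the 1967 of replicate 2.

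**Figure D2:**
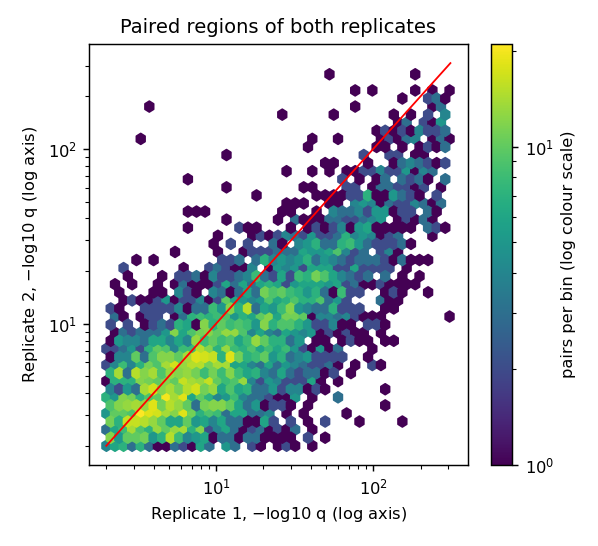
Each hexagon counts pairs of overlapping regions, with −log10 of the authors' q-value in replicate 1 on the x axis and in replicate 2 on the y axis, both on log axes. The red line marks equal values, and 74.7% of the 4167 pairs had the lower q-value in replicate 1 and so lie below it.

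The third question was what the authors' combined list holds. Of its 9051 regions, 4064 overlapped both replicates (44.9%, Wilson 95% interval 43.9 to 45.9), 2424 overlapped replicate 1 alone (26.8%, interval 25.9 to 27.7) and 1106 overlapped replicate 2 alone (12.2%, interval 11.6 to 12.9). The remaining 1457 regions overlapped neither (16%, interval 15.4 to 16.9). Regions found in both replicates were wide, with a median of 764.5 bp and a median q of 9.90e-22, whereas those found in neither had a median width of 127 bp and a median q of 8.52e-04. The widest combined region, chromosome IV 4792748 to 4823216, was 30469 bp wide with q = 1.05e-25 and overlapped no region of either replicate. It was chosen after its values were seen, and it is 1 of 10 combined regions whose internal structure changed when the authors moved coordinates between builds, per the file comments.

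The fourth question was how the X chromosome, of which hermaphrodites carry a pair, compares with the autosomes. The X chromosome held 947 of the 9051 combined regions (10.5%, Wilson 95% interval 9.85 to 11.1) on 17.7% of the chromosome length. That is 53.5 regions per Mb on X against 98.3 on the 5 autosomes, a ratio of 0.544 (two-sided exact binomial p = 4.55e-82, which measures counting error only). X was not the lowest chromosome. Chromosome V held 47 regions per Mb and chromosome II held 66.6, while chromosomes I, III and IV held 138, 139 and 121. X ranked second from the lowest among the 6 chromosomes (exact p = 0.333, where the smallest possible is 0.167).

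X regions were wide, so the difference nearly vanished in covered bases. The median X region measured 648 bp, against 313 bp on chromosome I, 306.5 bp on III, 344 bp on IV, 481 bp on II and 569 bp on V. Of the X chromosome 6.56% was covered, against 6.98% of the autosomes (ratio 0.940). Chromosome V had the lowest covered share, 5.04%, with 6.56% on II, 7.93% on I, 7.85% on III and 8.18% on IV. Chromosome V was also lowest in each replicate, but the order of I, III and IV was not stable: I was highest in replicate 1 (8.25%), III in replicate 2 (5.61%), and III (9.58%) when strong replicate regions absent from the combined list were added. The ratio of X to autosomes in regions per Mb was 0.533 in replicate 1 and 0.584 in replicate 2, and in covered bases 0.924 and 0.901. In the stronger 50% of the combined list by q the ratio of regions per Mb was 0.387, that is 19.6 on X and 50.7 on the autosomes. Regions with q below 1e-50 numbered 90 on X, 89 on II and 86 on V, against 238 on I, 222 on III and 238 on IV.

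**Figure D3:**
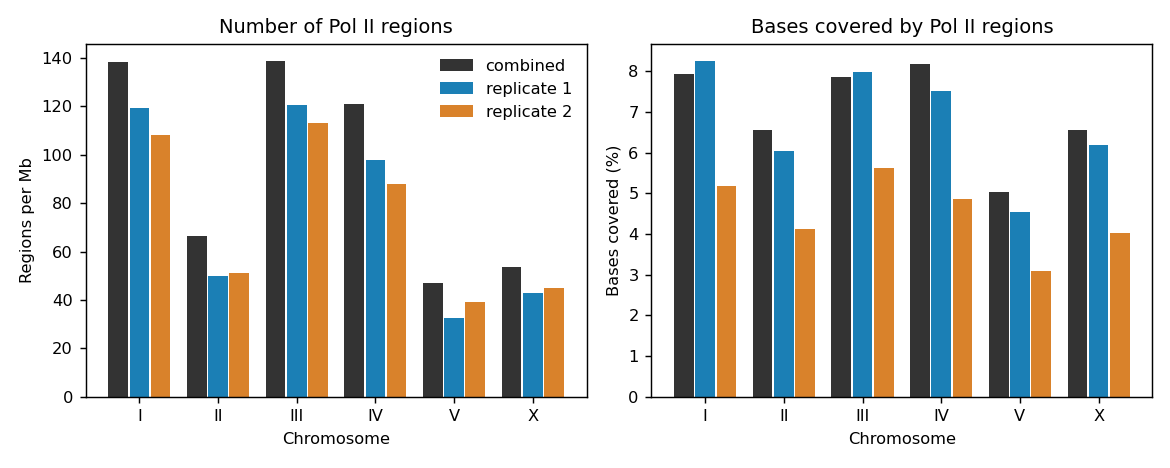
Bars give regions per Mb (left) and the percent of bases covered (right) for each chromosome in the combined list and in each replicate, with lengths taken up to the last region of any list. In regions per Mb, I, III and IV stand above II, V and X in all 3 lists, and in covered bases X (6.56% in the combined list) lies close to II (6.56%).

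The last question was whether chromosome centres, which are gene-rich in this species, differ from the repeat-rich arms. Each chromosome was divided into 3 equal parts, and all 6 were covered more in the central part than in the outer parts. The mean difference was 1.93 percentage points ± 0.774 (SD, n = 6 chromosomes; two-sided exact sign-flip permutation p = 0.0312, the smallest that 6 chromosomes allow). In the combined list, 7.22% of the centre and 3.94% of the arms were covered on chromosome V, 8.08% and 5.80% on chromosome II, and 8.62% and 7.59% on chromosome I. The order of chromosomes by this difference was not the same in each list: the difference was largest on V in replicate 1 (3.58 points) and on II in replicate 2 (2.3 points), and smallest on III (1.34 points) and I (0.762 points). The X chromosome had 7.65% in the centre and 6.02% in the arms, and its regions per Mb were 57.2 and 51.6, against 72.8 and 34.2 on chromosome V. The arms of 1 chromosome were not alike. The left arm of chromosome IV was covered to 8.78% and its right arm to 6.44%, and on chromosome III the left arm had 6.18% and the right arm 8.43%. The mean difference was 2.34 points in replicate 1 alone and 1.58 points in replicate 2 alone, positive on all 6 chromosomes in each. Covered shares are of total length. How much of the centres and arms 36-base reads can map to uniquely was not examined. A lower covered share of the arms is therefore not shown to be lower Pol II occupancy.

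**Figure D4:**
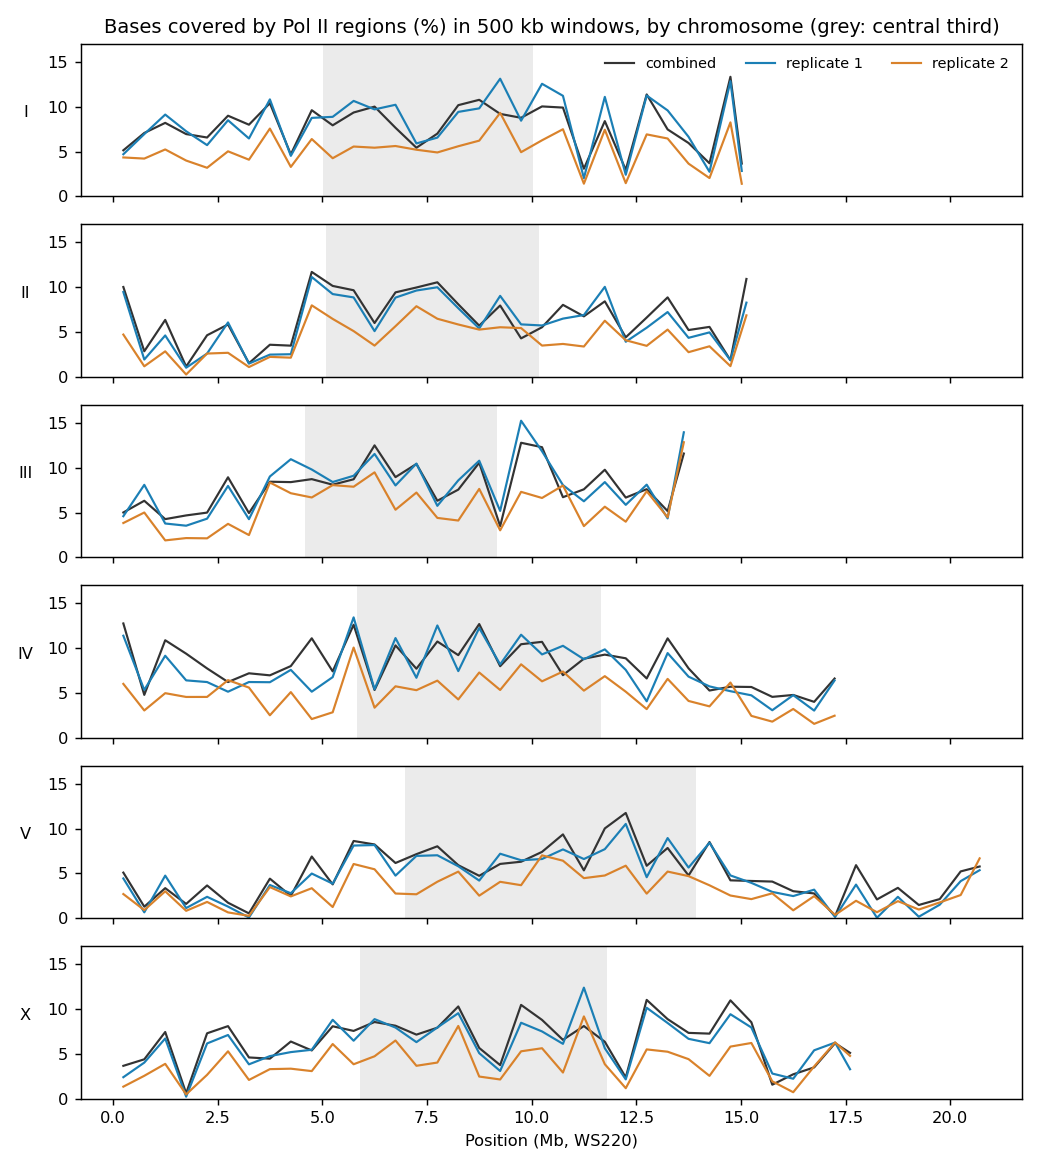
Lines give the percent of bases covered by Pol II regions in windows of 500 kb along each chromosome (x axis, position in Mb) for the combined list and each replicate, with the central part of each chromosome shaded. Chromosome V falls from 7.22% in its central part to 3.94% in its arms.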

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

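A signal in data outside the chromosome comparisons was found on the mitochondrial genome, which the comparisons leave out. Replicate 1 listed 1 mitochondrial region, 12247 to 12647, 401 bp wide, with q = 0.00138, at recovered rank 6376 among the regions tested. Neither replicate 2 nor the combined list held a mitochondrial region. Its origin was not tested.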

How the results depend on the processing

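The supplemented list, the list merged below 2000 bp, the weaker and stronger 50% of the combined list against whole replicate lists, the selection by q below 1e-20 and the covered bases of each replicate were chosen after seeing the data. Of the alternative values, 35 kept their direction and side of the threshold, or stayed within their spread, and 21 moved. Merging regions within 200 bp could hardly move any value, overlap shares included, since the shortest gap in each list was 200 bp. It left 9041, 7348 and 7114 regions in the combined, replicate 1 and replicate 2 lists, and its values are among the 35. None reversed. Excess overlap of the replicates stayed past the threshold under 5 alternatives in each direction, from 29.4% to 96.7% for replicate 1 and from 30.4% to 85.8% for replicate 2. The correlation of q-values ranged from 0.677 to 0.808 and the excess of centres over arms from 1.58 to 2.42 points.

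Keeping the stronger 50% of each list left 4526, 3680 and 3558 regions in the combined, replicate 1 and replicate 2 lists by construction. With all 3 lists reduced in this way, 47.5% of combined regions overlapped both replicates, 11.1% replicate 2 alone and 14.6% neither. With overlap of 50% of both regions, 22% overlapped both, 34.6% replicate 1 alone and 31.1% neither. Against the whole replicate lists, the stronger 50% of the combined list overlapped both in 78.6% of cases, replicate 1 alone in 17%, replicate 2 alone in 3.47% and neither in 0.884%, and the weaker 50% in 11.2%, 36.6%, 21% and 31.3%. The X to autosome ratio moved from 0.544 in regions to 0.940 in covered bases because X regions are wider, and in covered bases was 0.906 in the supplemented list, 0.924 in replicate 1 and 0.901 in replicate 2. Without either replicate, the ratio in regions lay between 0.533 and 0.584. It was 0.387 in the stronger 50% and 0.718 (38 against 53 per Mb) with regions less than 2000 bp apart merged. Other causes were not tested. The lists lack their strongest tested regions. What read depth limits was not tested, with 3262273 and 4623128 uniquely mapped ChIP reads behind replicates 1 and 2. No paired analysis was possible because the inputs have no region list here and no comparison of ChIP with input was made. No second score column exists in the lists, and the gene-level alternatives were not run.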

Other observations

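The windows, gaps and widest regions in this paragraph were chosen after their values were seen. Among full windows of 500 kb in the combined list, the highest cover lay at the right end of chromosome I, 14500001 to 15000000 (13.3% of bases), then on chromosome III, 9500001 to 10000000 (12.8%), and at the left end of chromosome IV, 1 to 500000 (12.8%). In replicate 1 these windows had 12.9%, 15.2% and 11.4%, and in replicate 2 they had 8.26%, 7.31% and 6.02%. The order depends on the regions that the combined list lacks. With strong replicate regions added, chromosome IV, 5500001 to 6000000, was highest (15.9%, against 12.6% in the combined list), and it was also highest in replicate 2 (10.1%). In the combined list, with or without the added regions, the lowest were on chromosome V, 17000001 to 17500000 (0.246%) and 3000001 to 3500000 (0.551%), and on X, 1500001 to 2000000 (0.613%), the window to the right of the strong X region at 1443320. In replicate 1 the lowest was chromosome V, 18000001 to 18500000 (0.064%, against 2.11% in the combined list), and in replicate 2 chromosome II, 1500001 to 2000000 (0.272%), while the named pair of windows on V came next in both replicates. The longest stretch of the combined list without a region was on chromosome V, 17268008 to 17846706 (579 kb), and replicate 2 had its longest at nearly the same place, 17267987 to 17857402. In replicate 1 the longest was on chromosome II, 3214459 to 3896899 (682 kb). The widest region of replicate 1 was on X, 11464276 to 11483308 (19033 bp, q = 2.03e-161), where replicate 2 had 4 regions. The widest region of replicate 2 was on chromosome I, 11669552 to 11681496 (11945 bp, q = 1.91e-191), inside a 16473 bp region of replicate 1 (q = 8.41e-274). Neither place is in the combined list.

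Of the tests below, those on merged regions and on regions called in replicate 1 alone were written before their results were seen, and all others after. No biological explanation was tested for any of these patterns, since the design has a single stage and a single antibody.

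The strongest tested regions are missing from all 3 lists used here, 262 from the combined list, 152 from replicate 1 and 71 from replicate 2. Lines lost without regard to strength are argued against, because 100.0% of pairs of lines with tied p-values, all but 1, implied the same starting rank from the first tie to the last, and so did the leading p-values, whereas in simulated lists with as many lines removed at random at most 11.4% did. Of 100 replicate 1 regions with q below 1e-200, 97 overlapped replicate 2 while 20 overlapped the combined list. That argues against absence of those places from replicate 2, but an overlap does not measure how strong they were there. Only 7 of 34 such replicate 2 regions overlapped replicate 1 (20.6%). Weakness or absence in replicate 1 stays open because its list lacks strong regions too. The smallest p-value behind a listed region was 1e-308 in replicate 1, 1e-307 in the combined list and 1e-304 in replicate 2. The smallest normal double-precision number is 2.2e-308, and no listed q equals 0. A candidate explanation is that p-values too small for the number format became 0 and their regions were dropped. The replicate 1 value lies just below that number and was still listed, so that number was not itself the cutoff. The replicate 2 value lies further from it. Replicate regions with q below 1e-20 that the combined list lacks form 251 places (122 in both replicates, 9 in replicate 1 only, 120 in replicate 2 only; 69 on chromosome III, 60 on I, 44 on IV, 29 on II, 26 on X and 23 on V), and adding them raises the combined cover from 6.92 to 7.99 Mb.

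Chromosomes I, III and IV held 2.41 times as many combined regions per Mb as II, V and X, a grouping made after seeing the counts. All listed q-values lie below the same threshold of 0.01, so a looser cutoff on I, III and IV was not a real alternative to test. The excess was larger among strong regions: the ratio was 3.07 among regions with q below 1e-50 and 1.12 among those with q of 0.001 or more. Broad occupied domains split into several regions could account for part of it: merging regions less than 2000 bp apart lowered the ratio to 1.78, between the bounds of 1.3 and 2 set beforehand, and this explanation stays open. In covered bases the ratio was 1.34. Gene density was not examined, since gene positions of this build were not used here.

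Replicate 1 covered 2.24 Mb more than replicate 2. Sequencing depth goes the other way, with 0.706 times as many uniquely mapped reads in replicate 1. Regions called in replicate 1 alone, less those in replicate 2 alone, held 0.880% of the difference, or 13.9% of the 2.58 Mb by which the lists differ once unshared regions with q below 1e-20 are left out of both as possible missing lines, and more of the strongest regions are missing from replicate 1 than from replicate 2 (a difference of -81). The excess therefore sat in regions that overlap the other list, 5.67 Mb in replicate 1 and 3.45 Mb in replicate 2. A difference in enrichment between the immunoprecipitations stays open and was not tested.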
